A study of Homo sapiens with 20 samples.

How the data were processed

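The series measured gene expression by RNA sequencing in 20 established human biliary tract cancer cell lines, with 1 library per line. The labels name poly(A) selection and a stranded library kit. A line is therefore the replicate, and every spread is a spread between lines. By anatomical site the lines comprise 7 from gallbladder cancer, 5 from extrahepatic and 4 from intrahepatic bile duct cancer, and 3 from the ampulla of Vater, where bile and pancreatic ducts enter the gut. The line OZ is labelled with both bile duct sites and was left out of the site comparisons, which used 19 lines. By origin, 13 lines came from a primary tumour, 6 from ascites and 1 from a liver metastasis. Replicate numbers follow the order of deposition only. The labels give no sequencing batch, and the repository that supplied each line (KCLB 6 lines, RIKEN 6, HSRRB 4, DSMZ 2, Zurich 2) was used in its place. In the fits with repository as a covariate, DSMZ and Zurich were merged into 1 level.

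The deposited table holds raw counts of reads per gene, in whole numbers, with no normalization by the authors. Per the labels, the tools were Trimmomatic, TopHat2 2.0.8, Picard 1.69 and featureCounts. The strand setting and the annotation release are not given in the sources used here, so genes that overlap on opposite strands may share reads. The table has 24222 entries, each a RefSeq identifier. Symbols were found for 23512 of them in a RefSeq gene table and for a further 354 in GENCODE metadata. The remaining 356 held 0.49% of all counts and kept their identifiers. No mitochondrially encoded gene is listed. The RefSeq table served for names and for the order of neighbouring genes only, since the reads had been aligned to an older genome build.

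Total counts per line ran from 10.47 M to 15.41 M (M for mega), with a median of 12.49 M. As a floor, a count of 0 was taken to allow up to 3 counts, which is 0.195 to 0.287 counts per M counts (CPM) of the unscaled total. Intervals on single-line values are exact Poisson 95% intervals of the count. Intervals and floors cover counting error only. CPM values use TMM-scaled library sizes.

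Comparisons of sites and of origin were fitted with edgeR 4.0.16 in R 4.3.3 (TMM, filterByExpr, robust quasi-likelihood F tests, two-sided). The site fit held 16615 genes and the origin fit 14843. Each site was contrasted with the unweighted mean of the other 3, intrahepatic with extrahepatic lines, and all 4 sites jointly in an omnibus test. Calls were made at a Benjamini-Hochberg adjusted p under 0.05. Common dispersion was 0.915 in the site fit and 0.783 in the origin fit. Recovery was tested on counts simulated with the dispersion of each gene and these group sizes. The 6 contrasts recovered 46.2% to 75.0% of genes given a log2 change of 3, and 0% to 6.0% given a log2 change of 1. Genes were drawn independently and every line of a group was shifted alike, so recovery in the real lines may differ.

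Gene lists for cell types, pathways and a panel of drug targets and tumour suppressors were fixed before the data were examined, as were the comparisons, tests and most alternatives. Of 29 lists, 27 had at least 5 measured members in the site fit and 23 in the origin fit. They were tested with camera of limma 3.58.1 with the correlation estimated per list. A list score is the mean over members of log2 CPM (prior count 2) minus the mean of each gene over the 20 lines. The epithelial minus mesenchymal score is the difference of those 2 list scores. Correlations are Pearson and Spearman with two-sided permutation p values, from 100000 permutations or exact for 6 lines, so the smallest p they can give is 1e-05. Each was recomputed without the 2 lines farthest from the median. Genes along the score were tested with limma (trend, robust) over 16555 genes, with both lists left out. Principal components used the 2000 most variable genes. A panel gene was called extreme in a line when log2(CPM + 0.5) lay at least 2.5 from the median of the lines and beyond 3 scaled median absolute deviations, with a median of at least 5 CPM for low calls.

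Genes were named by a fixed rule. Per contrast it takes up to 10 called genes in each direction, 15 for origin, and where fewer than 3 passed, the 3 of smallest p as values that did not pass. It also takes the 10 genes most correlated with the score at each end, all panel extremes, and 2 to 4 members of smallest p per list described. Some genes and loci that met it are not reported here. Genes outside it are said to have been chosen after their values were seen.

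Alternatives were RLE scaling, DESeq2 1.42.0 and limma-voom in place of edgeR, other count filters, non-robust dispersion, repository, origin or site as covariates, subsets of lines, other prior counts and thresholds, and each line left out in turn. Fits without HuH28, Mz-ChA-2 and SNU-245, tests of scores by origin, the interaction of origin with site, the relation of epithelial to mesenchymal score within repositories, values on each side of a gap in the epithelial score, and a scan along chromosomes were chosen after seeing the data. Other splits of the lines into groups of the same sizes were fitted 100 times with edgeR and 24 times with DESeq2, the real split included. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for scores, correlations and figures. No paired analysis was possible because no 2 lines are labelled as coming from 1 patient.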

Results

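Transcript counts were measured in 20 biliary tract cancer lines. The deepest library was TFK-1 with 15.41 M counts (M for mega) and the shallowest SNU-245 with 10.47 M, a ratio of 1.47. Totals in M were G415 14.29, HuH28 14.25, SNU-308 13.97, NOZ 13.7, Sk-ChA-1 13.5, TGBC14TKB 13.22, OCUG-1 13.12, SNU-1196 12.73, SNU-869 12.5. Lower totals in M were EGI-1 12.48, Mz-ChA-2 12.3, SNU-1079 11.88, OZ 11.87, TGBC2TKB 11.62, HuCCT1 11.52, TKKK 11.49, SNU-478 11.31, TGBC18TKB 10.74. Any pair of lines correlated at 0.641 to 0.888 across genes, where genes are not independent replicates. The series title speaks of molecular subtypes and drug targets, so the comparisons below take anatomical site, tumour origin, the main axis of variation and a panel of target genes.

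The lines differed most along an axis from epithelial to mesenchymal transcripts. At one end stood SNU-245, TKKK (score 3.94) and EGI-1 (3.45). SNU-245 had 2100 CPM of EPCAM, an epithelial adhesion molecule, and 1230 CPM of ELF3, an epithelial transcription factor. At the other end HuH28 had 13900 CPM of the matrix protein FN1, 8100 of COL1A1, 3820 of the matrix protease MMP2 and 1310 of the mesenchymal cadherin CDH2. In HuH28, 17 of the 32 mesenchymal genes were at their highest of all lines. The epithelial minus mesenchymal score ran from −10.39 in HuH28 to 5.15 in SNU-245, with 8 lines below 0 and 12 above. The leading principal component of the 2000 most variable genes held 21.2% of the variance and correlated with the score at 0.97.

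**Figure D1:**
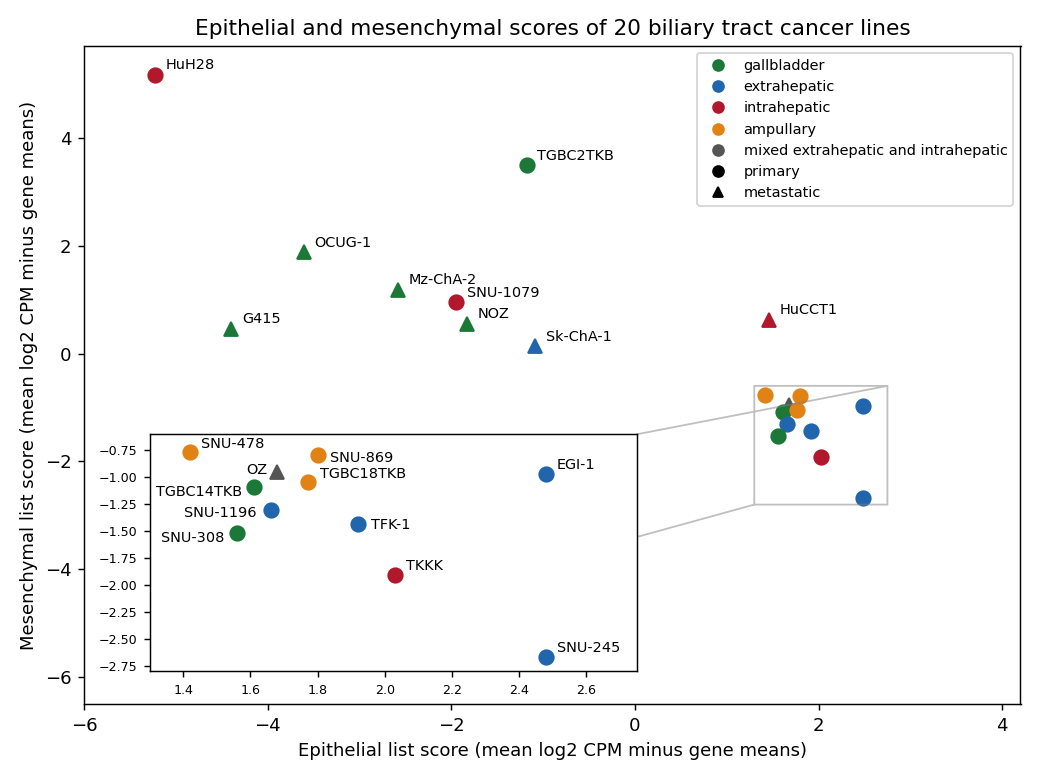
Each point is 1 of 20 lines, with its epithelial list score on the x axis and its mesenchymal list score on the y axis, both as mean log2 CPM minus gene means; colour gives the anatomical site, triangles are metastatic lines, and the inset enlarges the lower right. HuH28 sits at −5.23 and 5.17, and 12 lines lie at an epithelial score of 1.42 or more.

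The epithelial and mesenchymal scores ran in opposite directions over the 20 lines (r = −0.82, permutation p = 4e-05; rho = −0.83, p = 2e-05), and r was −0.84 without HuH28 and TGBC2TKB. By the rule fixed for the difference of the scores the lines formed no separate clusters. The epithelial score taken alone, however, left a gap of 2.5 log2 units, a share of 0.325 of its range, between 8 lower and 12 higher lines. Within the 12 higher lines r was −0.59 (permutation p = 0.0458; rho = −0.48, p = 0.12), and within the 8 lower lines −0.44 (permutation p = 0.273; rho = −0.4, p = 0.324). Each set spans a narrower range of the epithelial score, which lowers r by itself. Within the 6 KCLB lines r was −0.9 (exact permutation p = 0.0181), and within the 6 RIKEN lines −0.52 (exact permutation p = 0.293), but rho was −0.77 in both (exact permutation p = 0.103 each). The percent of counts in the 10 highest genes also followed the score (r = −0.82, permutation p = 3e-05; rho = −0.65), from 2.83% in TGBC14TKB to 6.2% in HuH28, where FN1 was the top gene. The TMM factor followed it by Pearson (r = 0.58, permutation p = 0.00802) but not detectably by Spearman (rho = 0.26, permutation p = 0.263) or without HuH28 and OCUG-1 (r = 0.21). Total counts did not detectably follow it (r = −0.34, permutation p = 0.143).

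Of 34 lists and receptor genes, 9 were correlated with the epithelial minus mesenchymal score after adjustment by Pearson permutation tests, 6 by Spearman tests and 5 by both. ERBB3, a receptor of the HER family, rose toward the epithelial end (r = 0.8, adjusted p = 0.00187; rho = 0.74), as did ERBB2 (r = 0.65, adjusted p = 0.0137; rho = 0.79). The gastric list, of mucosal secretory genes such as the trefoil factors, rose with them (r = 0.75, adjusted p = 0.00187; rho = 0.74), and so did the intestinal list (r = 0.56, adjusted p = 0.0472) and the squamous list (r = 0.55, adjusted p = 0.0472). Within the 12 lines of higher epithelial score the squamous r had the other sign (−0.31). Toward the mesenchymal end the fibroblast list rose (r = −0.71, adjusted p = 0.00714), as did the YAP targets (r = −0.69, adjusted p = 0.00714), the neuroendocrine list (r = −0.58, adjusted p = 0.0394) and the TGF-beta targets (r = −0.55, adjusted p = 0.0472). By Spearman the squamous (adjusted p = 0.0952), fibroblast (0.0952), neuroendocrine (0.114) and TGF-beta (0.0699) relations did not pass, and that of FGFR3 did (rho = 0.62, adjusted p = 0.0319; r = 0.46). Without HuH28 and OCUG-1 the relations of ERBB3 (0.78), ERBB2 (0.68), the gastric list (0.74) and the YAP targets (−0.72) still passed. FGFR2 then passed too (0.61, against 0.36 in all lines). The other 5 relations no longer passed, at r values of 0.51 for the intestinal and 0.48 for the squamous list, −0.53 for the fibroblast list, −0.43 for the neuroendocrine list and −0.32 for the TGF-beta targets. With 6 lines almost no r could pass after adjustment over 34 relations, so only the r values are compared within repositories. ERBB3 was at 0.85 and 0.95 in the 2 repositories, the YAP targets at −0.92 and −0.84, and the gastric list at 0.8 and 0.84, but ERBB2 at 0.24 and 0.79.

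Along the same score, limma called 1333 of 16555 genes outside both lists, 672 higher toward the epithelial end and 661 toward the mesenchymal end. The named genes of highest r on the epithelial side, apart from 1 entry without a symbol, were the serine protease gene PRSS22 (0.93), RBBP8NL (0.92), PRRG2 (0.92), the epiplakin gene EPPK1 (0.92), the ion transport regulator FXYD3 (0.91), the desmosome gene PKP3 (0.91), the lipid enzyme gene FA2H (0.91) and the ephrin receptor EPHA1 (0.9). FXYD3 ran from 0 to 929 CPM and PKP3 from 0.0871 to 237. On the mesenchymal side were LINC01139 (−0.91), SGTB (−0.9), the calcium-binding protein gene CALU (−0.9), SYT11 (−0.89), the integrin-linked talin TLN1 (−0.89), APMAP (−0.89), ARSB (−0.88), PDE1C (−0.88), the collagen prolyl hydroxylase P3H1 (−0.88) and CTIF (−0.87). CALU ran from 82.4 to 1890 CPM and P3H1 from 4.61 to 544. Each of these r values had a permutation p of 2e-05 or less. Leaving out HuH28 brought the count to 665 genes, 584 of them shared, and anatomical site as a covariate brought it to 354. Without HuH28, Mz-ChA-2 and SNU-245 it was 455.

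Among the 4 sites, 1 gene passed in the edgeR fit with site as the only term and all 19 lines. PIGR (NM_002644), the receptor that carries IgA across epithelia, was higher in ampullary lines than in the other sites by 8.90 on the log2 scale (SE 1.11, adjusted p = 0.00472), and it was the 1 gene past the omnibus test (adjusted p = 0.0173). Mean PIGR was 391 ± 336 CPM (SD, n = 3) in ampullary lines, 3.5 ± 5.74 (n = 5) in extrahepatic, 1.02 ± 1.43 (n = 4) in intrahepatic and 0.141 ± 0.138 (n = 7) in gallbladder lines. SNU-478 had 635 CPM and SNU-869 had 530, while TGBC18TKB had 8.25, below the 13.5 of the extrahepatic line TFK-1. The other 16 lines lay below all 3 ampullary lines. PIGR kept its call in each of the 19 fits without 1 line, but lost it with repository as a covariate (adjusted p = 1, log2 difference 9.99) and with origin as a covariate (adjusted p = 0.0624). Among primary lines alone it also missed the threshold (adjusted p = 0.0608), while PRSS21, chosen after its value was seen, passed (adjusted p = 0.0325). The omnibus call of PIGR was lost without EGI-1, Mz-ChA-2, NOZ, OCUG-1, SNU-308, SNU-478, SNU-869 or TGBC2TKB (0 genes each), and 2 genes passed without TGBC14TKB or without TKKK. In the omnibus test 1771 genes had an unadjusted p under 0.05 with edgeR and DESeq2 called 283, while the 1 gene of limma-voom was FAT3, not PIGR (FAT3 chosen after its value was seen).

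**Figure D2:**
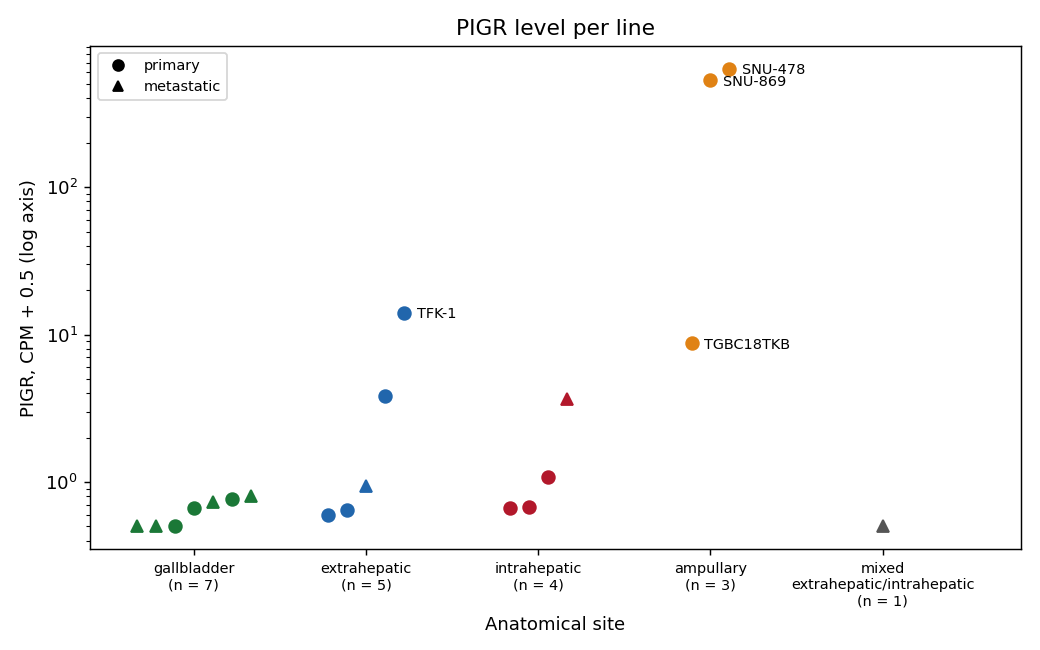
PIGR in CPM + 0.5 on a log axis for each of the 20 lines, by anatomical site, with circles for primary and triangles for metastatic lines. SNU-478 and SNU-869 stand at 635 and 530 CPM, and TGBC18TKB at 8.25 CPM.

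Other genes of the ampullary contrast did not pass in that edgeR fit. MANSC1 (log2 difference 4.88, adjusted p = 0.0897) owed its value to SNU-478, with 3960 CPM against at most 135 elsewhere. SULT4A1 (6.34, adjusted p = 0.115) was at 3.22 to 19.6 CPM in ampullary lines. Gallbladder lines overlapped that range, with 7.89 CPM in TGBC14TKB, 4.36 in SNU-308 and 4.18 in OCUG-1. ZNF606 (−5.81, adjusted p = 0.455) was at 0 to 0.578 CPM in ampullary lines. B3GLCT (−2.37) and LOC100506023 (−2.82) had larger p values still. With OZ taken as intrahepatic MANSC1 (adjusted p = 0.0339), SULT4A1 (0.049) and CXCL17 (0.049, chosen after its value was seen) passed beside PIGR, and with OZ taken as extrahepatic MANSC1 did (0.0416). SULT4A1 also passed by limma-voom (adjusted p = 0.029). Of the class II antigen presentation genes, 6 of 10 were higher in ampullary lines when adjusted over the list alone and 0 over all genes, HLA-DRA by 4.59 and HLA-DQB1 by 4.44. The class II score was 5.22 in SNU-869 but 0.15 in SNU-478 and −0.7 in TGBC18TKB, so 1 of the 3 lines carries the difference. The list itself did not pass (adjusted p = 0.753 with an estimated correlation). The immune list had the smallest list p (unadjusted p = 0.0432) but did not pass either (adjusted p = 0.753), and of its 7 tested members 1, LYZ at 3.73, had an unadjusted p under 0.05. In all, 873 genes had an unadjusted p under 0.05 with edgeR, DESeq2 called 133 and limma-voom 8. Without SNU-869 edgeR called 11 genes and without TGBC18TKB 3.

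Gallbladder lines were compared with the other sites. BCL2L15, a gene of the BCL2 family, averaged 0.528 ± 0.455 CPM (n = 7) in gallbladder lines, against 37.5 ± 25.9 (n = 5) in extrahepatic and 53.5 ± 57.4 (n = 3) in ampullary lines; in intrahepatic lines it was 12.1 ± 15.6 (n = 4). Its log2 difference was −5.76 (adjusted p = 0.114). The kinase gene MAP3K1 differed by −1.83 (19.6 ± 8.23 CPM in gallbladder lines) and PDXK, which makes vitamin B6 active, by −1.34. On the other side were LRRTM4 (5.05), with at most 4.7 CPM, the tubulin gene TUBB4A (5.32) and FGD1 (2.57, 20.5 ± 13.8 CPM against 3.22 ± 1.97 in extrahepatic lines). None passed with edgeR, where 2051 genes had an unadjusted p under 0.05. DESeq2 called 382 genes and limma-voom 0. With origin as a covariate edgeR called BCL2L15 and MAP3K1 lower and LRRTM4 and FAM95A higher, the last chosen after its value was seen. Without HuH28 it called 3 genes.

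Bile duct, WNT and epithelial lists were all lower in gallbladder lines, and none passed camera with an estimated correlation. The biliary list had a median log2 difference of −1.54 (unadjusted p = 0.00849, adjusted p = 0.183 with an estimated correlation). Its member ANXA4 differed by −2.11, PKHD1, a gene of bile duct cilia, by −4.56, and MUC1 by −2.10, while ONECUT1 stood at 5.10. None of its 19 members passed when adjusted over the list alone. The WNT targets had a median of −1.66 (unadjusted p = 0.0135, adjusted p = 0.183), and 4 of 17 were lower when adjusted over the list alone: ZNRF3 (−1.60), AXIN2 (−3.08), LGR5 (−4.60) and TNFRSF19 (−4.31). The mesothelial list had an unadjusted p of 0.0353, with UPK3B at −4.65. The epithelial list had a larger median change (−2.33) but a larger p (unadjusted p = 0.0757, adjusted p = 0.481; 0.0443 and 0.299 by the directional test of fry). The epithelial score averaged −3.11 ± 1.13 in the 4 metastatic gallbladder lines but 0.66 ± 1.6 in the 3 primary ones. Only 1 extrahepatic and 1 intrahepatic line of the fit are metastatic, so the lower epithelial list is not separated from origin. Whether biliary genes were lower beyond epithelial genes in general was not tested. No list passed by camera with an estimated correlation or by the directional test of fry. The mixed test of fry, which takes changes in either direction, called the biliary list (adjusted p = 0.0101) and the WNT targets (adjusted p = 0.0209), and camera with a preset correlation of 0.01 called 11 lists. Without HuH28 the biliary list passed (adjusted p = 0.0298).

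Intrahepatic lines held matrix genes and a bile acid enzyme at high levels in single lines. COL5A2, a fibrillar collagen gene, was at 1490 CPM in HuH28 and 107 in HuCCT1 but at 0.841 in TKKK (log2 difference 7.4, adjusted p = 0.0836). THBS2 was at 2950 CPM in HuH28 and at most 10.6 elsewhere (9.22, adjusted p = 0.0836). BAAT, which joins bile acids to amino acids, was at 77 CPM in SNU-1079 and 15.6 in TKKK (6.62, adjusted p = 0.0836). HOXB13, a posterior homeobox gene, had no count in any of the 4 lines, against 6.2 ± 2.42 CPM (n = 5) in extrahepatic and 10.3 ± 3.32 (n = 3) in ampullary lines (adjusted p = 0.118). In gallbladder lines it was 3.78 ± 3.87 (n = 7), with 0 in G415 and 0.0845 in TGBC2TKB. COX7A2 (−1.25) and NANS (−1.38) had adjusted p values of 0.148 and 0.164. Of 30 mesenchymal genes, 13 were higher when adjusted over the list alone, among them COL3A1 (9.73), TAGLN (4.74), MMP2 (9.01) and THY1 (9.03), and 1 was lower, S100A4 (−3.74), with 0 in either direction over all genes. The list had an adjusted p of 0.603 with an estimated correlation, and HuH28 held the highest value of COL3A1, TAGLN, MMP2 and THY1. Of 8 fibroblast genes 3 were higher over the list alone, MFAP4, FAP and ACTA2, and 0 over all genes (adjusted p of the list = 0.603 with an estimated correlation). The fibroblast score was 4.95 in HuH28, 1.2 in SNU-1079, −0.14 in HuCCT1 and −1.04 in TKKK. edgeR called 0 genes, with 1574 at an unadjusted p under 0.05, against 267 by DESeq2 and 3 by limma-voom (FAT3, SLC35F3 and CDH6, chosen after their values were seen). Without HuCCT1 edgeR called 7 genes, without TKKK 4, without TGBC2TKB 2, and 1 without EGI-1, HuH28, OCUG-1 or SNU-1079.

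Extrahepatic lines had the smallest p values in genes that 1 or a few of them carried and in genes that all 5 held at low levels. LGALS4, an intestinal lectin gene, was at 1240 CPM in SNU-245 and at most 3.25 in the other lines (log2 difference 8.69, adjusted p = 0.178). PPP1R1B was at 947 CPM in SNU-245 and 282 in SNU-1196 but at 0.0699 in TFK-1 (8.59), and DPEP1 was at 75 CPM in SNU-245 (6.49). CALD1, an actin-binding protein gene, averaged 2.1 ± 3.45 CPM (n = 5), against 266 ± 215 (n = 7) in gallbladder and 954 ± 1240 (n = 4) in intrahepatic lines (−7.02, adjusted p = 0.178). SNRPN, a gene transcribed from the paternal copy, was at 0.888 CPM or less in all 5 extrahepatic lines (−8.15, adjusted p = 0.194). Low SNRPN was not confined to this site: the gallbladder line OCUG-1 had 0 CPM, the intrahepatic line HuCCT1 0.0852 and OZ 0.249. SNURF, which lies within SNRPN, had identical counts. Of 20 intestinal genes 11, and of 13 gastric genes 3, were higher when adjusted over the list alone, and 6 of 10 class II genes were lower, but 0 of them over all genes. The intestinal score was 7.24 in SNU-245 and at most 0.41 in the other 4 extrahepatic lines. TFF2 stood at 4.21 and HLA-DRA at −5.80. The intestinal and class II lists missed the threshold (adjusted p = 0.342 each with an estimated correlation), as did the gastric list (adjusted p = 0.358) and the WNT targets (median 1.39, unadjusted p = 0.0335, adjusted p = 0.342), with LGR5 at 4.31 and AXIN2 at 2.23. edgeR called 0 genes, with 1164 at an unadjusted p under 0.05, against 188 by DESeq2 and 0 by limma-voom. Without NOZ or without TGBC14TKB it called 1.

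Intrahepatic lines were also set against extrahepatic lines, the classical division of bile duct cancer. CALD1 had the smallest p of the contrast (log2 difference 8.82, adjusted p = 0.17), at 151 CPM or more in each intrahepatic line and 8.23 or less in each extrahepatic line. BAAT (8.03), COL5A2 (8.14), HOXB13 (−9.29), PLPBP (−1.67) and ALDH3A2 (−1.62) each had an adjusted p of 0.411. Of 30 mesenchymal genes 11 were higher over the list alone, COL3A1 by 10.73 and MMP2 by 12.78, and 1 was lower, S100A4 by −6.27. None of them passed over all genes, and the list had an adjusted p of 0.36 with an estimated correlation. The mesenchymal score was 5.17 in HuH28, 0.95 in SNU-1079, 0.63 in HuCCT1 and −1.91 in TKKK, so HuH28 weighs heavily here. The neuroendocrine list had the smallest list p (unadjusted p = 0.0386) but did not pass (adjusted p = 0.36), with the granule gene SCG2 at 6.79 and SYP at 1.86. Its score was 2.55 in HuH28, 0.63 in SNU-1079, −0.01 in TKKK and −1.02 in HuCCT1. edgeR called 0 genes, with 1562 at an unadjusted p under 0.05, against 298 by DESeq2 and 0 by limma-voom; without EGI-1 it called 1.

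Lines from metastases were compared with lines from primary tumours. BLNK, an adaptor of B cell receptor signalling, was at 0.0779 CPM or less in all 7 metastatic lines and at 8.91 ± 13.3 CPM (n = 13) in primary lines (log2 difference −8.12, adjusted p = 0.247). NEXN, an actin filament gene, was at 15.7 ± 12.2 CPM (n = 7) against 1.27 ± 1.33 (n = 13) (3.61, adjusted p = 0.247). In the metastatic lines OZ and Sk-ChA-1, which are not gallbladder lines, NEXN was at only 0.997 and 1.19 CPM. TRPV2, a calcium channel gene, was at 243 CPM in NOZ, 241 in G415 and 135 in OCUG-1, all gallbladder lines, and at 0 in Sk-ChA-1 (6.08). The decoy receptor gene TNFRSF6B was at 155 ± 141 CPM against 12.6 ± 16.6 (3.61), though it overlaps a read-through gene. ANKRD6 (−3.58) and CNNM4 (−1.72) were lower with an adjusted p of 0.273. MAPK output, the feedback genes of that kinase cascade, had the smallest list p (median 0.85, unadjusted p = 0.021, adjusted p = 0.482 with an estimated correlation), and SPRY4 (2.40) and SPRY2 (1.65) passed when adjusted over the list alone. The epithelial list had a median of −2.26 (adjusted p = 0.665). No gene passed with edgeR, where 1149 had an unadjusted p under 0.05; DESeq2 called 181 and limma-voom 0, and without OZ edgeR called 1. All 6 KCLB lines are primary, so origin is partly bound to repository. It is partly bound to site too, since 4 of the 7 metastatic lines are gallbladder lines and all 3 ampullary lines are primary.

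The epithelial score, tested by origin after the scores were seen, averaged −1.48 ± 2.35 (n = 7) in metastatic and 0.8 ± 2.25 (n = 13) in primary lines (two-sided exact permutation p = 0.0424, adjusted p = 0.127 over 6 tests). Leaving out any 1 of 15 lines ended even the unadjusted call, up to an exact permutation p of 0.104 without G415. Within gallbladder lines the means were −3.11 ± 1.13 (n = 4) and 0.66 ± 1.6 (n = 3) (exact permutation p = 0.0286, the smallest of 35 arrangements, adjusted p = 0.127). The epithelial minus mesenchymal score did not differ detectably, at −2.03 ± 2.99 (n = 7) and 1.1 ± 4.4 (n = 13) (exact permutation p = 0.112), but without HuH28 the difference was −4.09 (exact permutation p = 0.0111). By site that score averaged 2.74 ± 2.37 (n = 5) in extrahepatic, 2.52 ± 0.32 (n = 3) in ampullary, −2.13 ± 6.18 (n = 4) in intrahepatic and −2.2 ± 3.61 (n = 7) in gallbladder lines. Site accounted for 33.4% of its variance (permutation p = 0.0915).

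The panel of 99 drug target and suppressor genes held 56 extreme values, 32 high and 24 low, and every line had at least 1. CCND3, a cyclin of the G1 phase, was at 1380 CPM in SNU-1196 and 511 in TFK-1 against a median of 55.8. Its 5 listed neighbours were at their highest in SNU-1196, BYSL at 485 CPM, and not in TFK-1, where TRERF1 lay at −1.70.

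Receptor kinase genes were extreme in single lines. HuH28 had 185 CPM of KIT, 177 of ROS1, 136 of PDGFRA, 14.5 of ALK, 5.14 of PDGFRB and 2.44 of NTRK2. ROS1 was also high in TGBC2TKB (38.7), SNU-478 (14.6) and SNU-1079 (9.92), KIT in TFK-1 (16.6), PDGFRA in Mz-ChA-2 (79.7) and OCUG-1 (3.18), and PDGFRB in Mz-ChA-2 (8.18) and SNU-1079 (6.95). NTRK2 was at 56.5 CPM in TFK-1, 2.92 in SNU-869 and 2.83 in Sk-ChA-1. EGFR was low in TGBC14TKB (9.76 against a median of 84.9) and AXL in SNU-308 (2.52) and TGBC14TKB (1.59), against a median of 213. MYCN was at 40.0 CPM in OZ, 20.5 in TGBC14TKB, 9.86 in SNU-245 and 6.94 in SNU-1196, and CCND2 at 33.7 in OCUG-1 and 29.1 in SNU-245. The immune target IDO1 was at 30.5 CPM in HuCCT1, 20.5 in Sk-ChA-1 and 5.98 in TGBC18TKB. CLDN18, an antibody target, was at 12.4 CPM in TKKK. ERBB2, FGFR3 and FGFR4 met no rule for an extreme, and their values were chosen after they were seen. ERBB2 was at 2230 CPM in TKKK and 1450 in TGBC18TKB against a median of 229, with its neighbour GRB7 at 894 and 346. Mz-ChA-2 had 1390 CPM of FGFR3 and 535 of FGFR4.

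**Figure D3:**
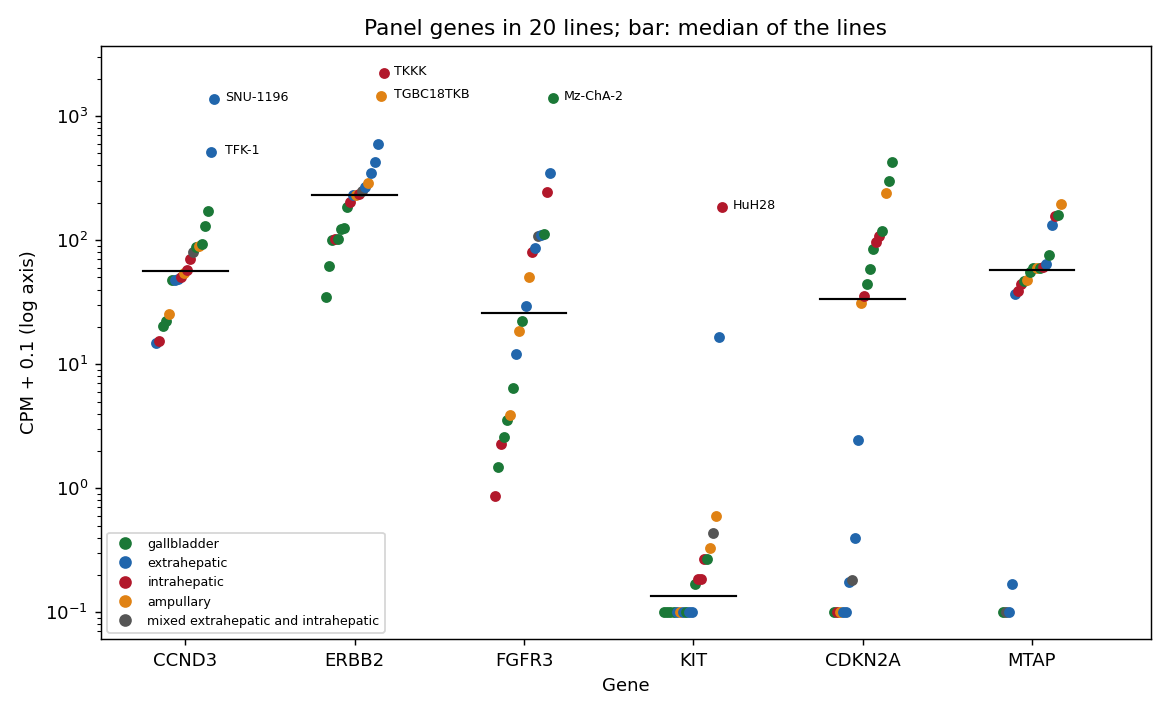
Each point is 1 of 20 lines, as CPM + 0.1 on a log axis, for 6 panel genes, with colour by anatomical site and a bar at the median. CCND3 reaches 1380 CPM in SNU-1196, ERBB2 2230 in TKKK and FGFR3 1390 in Mz-ChA-2, while MTAP is at or near 0 in 4 lines.

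Suppressor genes were low in single lines or in a few. MTAP, which neighbours CDKN2A and recycles methionine, had 0 counts in EGI-1, Mz-ChA-2 and OZ and 1 count in TFK-1, against a median of 57.2 CPM. A count of 0 allows up to 0.253 CPM in OZ and less in the other 2. CDKN2A itself, chosen after its values were seen, had at most 3 counts in 7 lines. ARID2, a chromatin remodelling gene, had 0 counts in SNU-308 (median 40.5 CPM). STK11 was at 0.699 CPM in TFK-1 and 4.79 in SNU-478 (median 57.2). The DNA repair gene MGMT had 0 counts in EGI-1 and Mz-ChA-2 and 2 in TGBC2TKB (median 14.4 CPM). RB1 was at 11.3 CPM in TGBC14TKB (median 69.2) and CDKN1A at 3.11 in Mz-ChA-2 (median 42.1). CDH1, the epithelial cadherin, was at 0.697 CPM in OCUG-1, 0.954 in G415 and 1.78 in SNU-1079 (median 296). It was also low in HuH28 (4.96) and NOZ (4.94), which did not meet the rule. ELF3 was at 0.294 in G415, 0.348 in HuH28, 9.88 in TGBC2TKB and 15.5 in NOZ (median 317). CDH1 and ELF3 belong to the epithelial list, and each line named for them was among the 8 of lower epithelial score. Their low values are therefore not separate from the main axis. With 1 library per line these are single measurements with no test.

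In some lines the genes of a list stood far above their level in the other lines. SNU-245 stood at an intestinal score of 7.24 (next OZ, 2.57), and 21 of 24 intestinal genes were at their highest there. REG4 was at 2330 CPM, the fatty acid binding protein FABP1 at 2010 and the cadherin CDH17 at 1520, while MUC2 was at 0.0986. Mz-ChA-2 stood at a hepatocyte score of 4.87 (next SNU-478, 1.53), with 16 of 23 genes at their highest. The plasma protein genes SERPINA1, AMBP and TTR were at 4640, 1080 and 469 CPM, but ALB, the gene of serum albumin, was at 9.42. SNU-308 stood at a squamous score of 4.43, with 9 of 21 genes at their highest, the keratin KRT6A at 1710 CPM and TP63, the squamous transcription factor, at 583. TKKK had the highest biliary score (2.96), with ANXA4 at 2490 CPM, and also the highest mesothelial score (2.79), though 1 of 10 mesothelial genes, UPK1B at 231 CPM, was at its highest there. G415 had the highest endothelial score (2.79), with 4 of 9 genes at their highest, a median log2 excess of 0.44 over the list, the angiopoietin receptors TIE1 at 319 and TEK at 85 CPM, and VWF at 16.1. HuH28 had the highest fibroblast score (4.95, 5 of 10 genes at their highest). It also had the highest neuroendocrine score (2.55), which few genes carried: 2 of 12 were at their highest, SCG2 at 454 CPM among them, and the median log2 excess was 0.17.

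**Figure D4:**
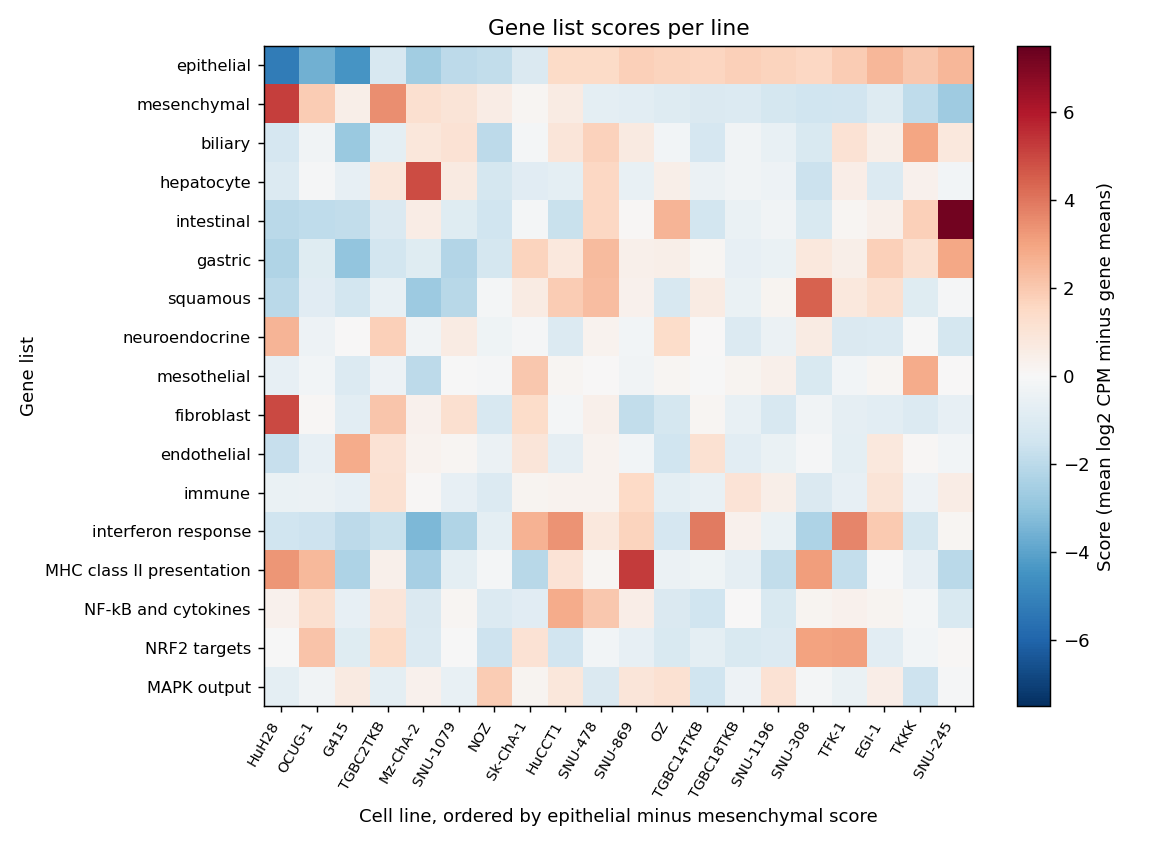
Scores of 17 gene lists (y axis) in 20 lines (x axis, ordered by epithelial minus mesenchymal score), in mean log2 CPM minus gene means, red high and blue low. The highest value is 7.24, the intestinal score of SNU-245, and the hepatocyte score of Mz-ChA-2 is 4.87.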

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

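All tests of explanations in this part were chosen after the results they measure had been seen. A line was singled out where its gap to the nearest line exceeded Dixon's 95% critical value within its site group or among the metastatic lines. In 199 groups of values 25 values were singled out, and chance gives about 1 in 20, or 9.9. The 25 are not independent: 3 are values of SNURF identical to those of SNRPN, and the hepatocyte score of Mz-ChA-2 counts in 2 groups.

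Mz-ChA-2 stood apart from the other gallbladder lines in its hepatocyte score of 4.87, where the next gallbladder line had 0.83, and from the other metastatic lines, where the next had 0.44. Hepatocytes or liver tissue in the sample would bring ALB at or above the level of SERPINA1, but ALB reached 0.203% of it, and 8 of the 23 genes lay below 10 CPM, among them CPS1 at 0.779 and CYP3A4 at 0 (CPS1 and CYP3A4 chosen after they were seen). The label names a liver metastasis, which makes this an obvious candidate source, yet the levels argue against it. A mislabelled line stays open: the closest other line had r = 0.784, and a line from outside the series would leave no trace here. No biological explanation was tested, since no other line is labelled as a liver metastasis. The primary intrahepatic lines HuH28, SNU-1079 and TKKK had hepatocyte scores of −1.03, 0.67 and 0.3.

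HuH28 formed the mesenchymal end of the score. Fibroblasts in the sample would bring COL1A2, SPARC, DCN and LUM near the level of COL1A1, but the highest of them, DCN, reached 0.615% of it. These 4 genes were picked after their values were seen and bear on the source of COL1A1 only. The fibroblast list as a whole was highest in HuH28 (4.95, next TGBC2TKB, 2.08), with 5 of 10 genes at their highest. For those genes fibroblasts in the sample stay open. A few genes taking most of the counts would lower the epithelial and the mesenchymal score together, apart from list members among those genes. In HuH28 the 10 highest genes held 6.2% of the counts, which is not most of them. The 2 scores ran in opposite directions over the lines (r = −0.82). That value was known beforehand and cannot exclude a smaller effect of this kind. The 10 highest genes, FN1 first, are themselves partly mesenchymal, so their share may follow from the score. No biological explanation was tested, since the labels give none for this line.

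Among gallbladder lines, Mz-ChA-2 was also highest in the intestinal score (0.53, next −1.09) and in log2(CPM + 0.5) of BAAT (0.87, next −0.13). TGBC14TKB had an interferon response score of 3.89 (next −0.72), and OCUG-1 had log2(CPM + 0.5) of −1.0 for SNRPN and SNURF (next 5.05).

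Among extrahepatic lines, SNU-245 stood apart in the intestinal score (7.24, next 0.41), in LGALS4 (10.27, next 1.91) and, near the floor, in SNRPN and SNURF (0.47, next −0.80). Sk-ChA-1, the 1 metastatic line of this site, had an epithelial score of −1.09 (next 1.66), a mesothelial score of 2.0 (next 0.41) and a fibroblast score of 1.38 (next −0.64). EGI-1 had a class II presentation score of −0.03 (next −1.81), and SNU-1196 had a log2(CPM + 0.5) of −0.80 for LRRTM4, from 1 count.

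Among intrahepatic lines, HuCCT1 stood apart in the interferon response (3.38, next −1.33), cytokine (2.77, next 0.31) and NRF2 scores (−1.43, next −0.21), and in SNRPN and SNURF (−0.77, next 4.93). HuH28 had a total of 14.2 M counts (next 11.9). SNU-1079 was low in FGD1 (1.19, next 1.75), and TKKK was high in LGALS4 (1.43, next −0.58) and, near the floor, in SULT4A1 (−0.78, next −1.0).

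The effect of origin differed between gallbladder lines and the other lines for 1 gene of 16672 in edgeR, the receptor phosphatase gene PTPRU (log2 difference of effects −5.41, adjusted p = 0.0134). It averaged 4.68 ± 3.93 CPM (n = 4) in metastatic and 141 ± 133 (n = 3) in primary gallbladder lines, and 149 ± 29.2 (n = 3) and 106 ± 29.2 (n = 10) in the others. This interaction was added after seeing the data.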

How the results depend on the processing

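RLE scaling, other count filters and non-robust dispersion kept every count of called genes from edgeR within 1.5 times. DESeq2 called far more genes: 382 for gallbladder, 267 for intrahepatic, 188 for extrahepatic and 133 for ampullary lines, 298 for intrahepatic against extrahepatic, 283 in the omnibus test and 181 for origin. Other splits into the same group sizes gave DESeq2 a median of 134 for gallbladder, 120 for intrahepatic and 100 for extrahepatic lines. The median was 104 for ampullary lines and 129 for intrahepatic against extrahepatic. A large count by DESeq2 therefore does not by itself mark a site difference. limma-voom called 3 for intrahepatic and 8 for ampullary lines. Repository as a covariate gave 0 for ampullary lines and 0 in the omnibus test, and origin as a covariate gave 4 for gallbladder lines, 0 for ampullary lines and 0 in the omnibus test, which was also 0 among primary lines. OZ taken as intrahepatic gave 4 ampullary genes and as extrahepatic 2. Without HuH28, Mz-ChA-2 and SNU-245, an alternative chosen after seeing the data, there were 4 for gallbladder lines and 0 in the omnibus test. The cause was not tested.

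With 1 line left out at a time, the counts of called genes ranged from 0 to 3 for gallbladder, 0 to 7 for intrahepatic, 0 to 1 for extrahepatic and 1 to 11 for ampullary lines, 0 to 1 for intrahepatic against extrahepatic, 0 to 2 in the omnibus test and 0 to 1 for origin. HuCCT1 (7, intrahepatic), SNU-869 (11, ampullary) and HuH28 (3, gallbladder) gave the highest. PIGR kept its ampullary call in 28 of 31 fits, but 19 of these fits leave out 1 line each and share most of their data. The 3 losses were with repository or origin as a covariate and among primary lines alone. Of 100 splits into the same sizes, the real one included, 76 called at least 1 ampullary gene. Of 1132 further values of named genes in other fits, 32 of 35 from DESeq2 and 21 others newly passed.

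With a preset correlation of 0.01, camera called 11 lists for gallbladder, 8 for intrahepatic, 15 for extrahepatic and 8 for ampullary lines, 18 for intrahepatic against extrahepatic and 6 for origin, against 0 each with an estimated one. The preset value is far below most estimates. With 1 line left out the gallbladder count was 0 to 1 (1 without HuH28) and the other 5 stayed at 0.

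The epithelial against mesenchymal r stayed past its threshold with other scaling, prior count, filter and scores of scaled genes, and at −0.87 to −0.75 with 1 line left out. It missed it within RIKEN lines (−0.52) and within the 8 lines of lower epithelial score (−0.44), both chosen after seeing the data, where fewer lines and a narrower range were tested. Relations past adjustment fell from 9 to 5 without the 2 farthest lines. Those 5 were ERBB3, ERBB2, the gastric list and the YAP targets, which had passed in all lines, and FGFR2, which had not. The counts within KCLB (0), RIKEN (0) and each side of the gap (0 within 8 lines, 0 within 12 lines) say little about stability, since 6 lines could hardly pass and each side of the gap spans a narrower range by construction. The squamous r reversed to −0.31 in the 12 higher lines. Genes along the score numbered 354 with site as a covariate, 455 without HuH28, Mz-ChA-2 and SNU-245, and 665 (without HuH28) to 1422 with 1 line left out. The leading component held 25.2% of the variance with 500 genes and 19.2% with 5000. Panel extremes stayed at 49 to 64.

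By origin, the difference in the epithelial score was −2.28 and −2.81 to −1.79 with 1 line left out, and that of the epithelial minus mesenchymal score −4.09 (without HuH28) to −2.55. Leaving out EGI-1, G415, Mz-ChA-2, NOZ, OCUG-1, Sk-ChA-1, SNU-1196, SNU-245, SNU-308, SNU-478, SNU-869, TFK-1, TGBC14TKB, TGBC18TKB or TKKK ended the unadjusted call for the epithelial score (−2.35 to −1.79, exact permutation p up to 0.104). Depth of 10.47 to 15.41 M counts limits values near the floor, such as LRRTM4 and SULT4A1. Every alternative fixed in advance was run.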

Other observations

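Programs other than lineage also stood out in single lines. TGBC14TKB and TFK-1 had interferon response scores of 3.89 and 3.68, with IFI6 at 2800 CPM and ISG15 at 760 in TGBC14TKB. SNU-869 had a class II presentation score of 5.22 (next HuH28, 3.33), with CD74 at 1520 CPM and HLA-DRA at 254, and the highest immune score (1.51), though none of the 15 immune genes was at its highest there. Sk-ChA-1 had the highest class I score (1.78). TFK-1 and SNU-308 had NRF2 scores of 3.06 and 3.02; in TFK-1 the oxidative stress genes AKR1C1, NQO1 and TXNRD1 were at 3320, 2670 and 2660 CPM. HuCCT1 had a cytokine score of 2.77, with CXCL5 at 492 CPM. NOZ had the highest MAPK output score (1.90), with FOSL1 at 734 CPM and DUSP6 at 703.

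SNU-245 also had the highest scores for WNT targets (3.03, AXIN2 at 237 CPM and LGR5 at 85.4), gastric genes (2.91), hypoxia and glycolysis (1.72, NDRG1 at 1250 CPM), immediate early and heat shock genes (0.93) and epithelial genes (2.48). HuH28 was highest in YAP targets (1.47, CCN2 at 981 CPM) and TGF-beta targets (1.88). G415 was highest in proliferation (1.10), SNU-478 in cholesterol synthesis (0.72), TGBC2TKB in unfolded protein and amino acid stress (0.89) and TKKK in histone genes (2.45). Of the 12 pancreatic acinar genes 2 passed the filter, so that list was not tested, and none of the 13 mitochondrially encoded genes was listed.

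The tests in the rest of this part were chosen after the results were seen. Windows of 10 neighbouring genes were scanned along the chromosomes after the panel had been seen, over 12400 genes. Each gene counted with its log2 excess over the median, capped at 3, so a window mean near 3 is a lower bound of its size. In 97 high and 95 low windows the mean passed the highest of 100 shuffles of gene order, a loose standard since neighbouring genes share regulation and clusters such as the protocadherins share exons. SNU-1196 had a high window on chromosome 6 around CCND3 (2.99). TKKK had a high window on chromosome 17 from RPL19 to GRB7 (2.60), which holds ERBB2, and TGBC18TKB from TCAP to THRA (2.05) and on chromosome 7 from STAG3 to NYAP1 (2.90). Mz-ChA-2 had a low window on chromosome 9 from ACER2 to TUSC1 (−2.81), which holds CDKN2A and MTAP. SNU-478 had a high window on chromosome 12 from TAS2R14 to CREBL2 (2.10), and near MANSC1 its genes LRP6, DUSP16, BCL2L14, ETV6 and BORCS5 were at 4450, 1620, 482, 399 and 148 CPM, all chosen after they were seen.

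Other splits of the lines into groups of the same sizes gave results as large as the real ones, so chance could not be excluded for any contrast. For genes at an unadjusted p under 0.05, the real count was matched by 10 of 100 splits for gallbladder (2051, highest other 2966), 23 for intrahepatic (1574, 2913), 65 for extrahepatic (1164, 2161), 16 for intrahepatic against extrahepatic (1562, 2544) and 24 for origin (1149, 1986). The 1 gene called for ampullary lines was matched in number by 76 of 100 splits (highest other 107) and that of the omnibus test by 42 (highest other 77). For lists at an unadjusted p under 0.05, 57 of 100 splits gave at least the real 7 (highest other 15). Counts by DESeq2 were matched in 3 of 24 splits for gallbladder (382, highest other 513), 4 for intrahepatic (267, 418), 6 for extrahepatic (188, 275), 10 for ampullary lines (133, 552) and 2 for intrahepatic against extrahepatic (298, 429). The median of the other splits was 4 genes for ampullary lines, against the real 1, and 0 for the omnibus test. Splits that call several times the real number point to some structure of the lines, and no structure was tested as the reason.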
